A study of Mus musculus with 9 samples.

How the data were processed

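RNA was sequenced from splenic type 2 conventional dendritic cells (cDC2s) of C57BL/6 mice, 3 libraries from each of 3 genotypes: wild-type (WT), CD97-deficient (the gene Adgre5, listed under its older symbol Cd97) and Gα13-deficient (Gna13 deleted with a Cre recombinase driven by the CD11c promoter). The deposited table holds whole-number counts per gene symbol that the authors made from their reads. STAR, HTSeq, DESeq2 and the mm10 genome build are named without versions in the submitters' processing notes. The library preparation, per the labels, followed standard Illumina protocols with no further detail, and whether counting used strand is not given in the sources used here. All 9 source names in the labels carry lane 6. The table lists 14209 genes, none with a total under 10 counts over the 9 libraries, so genes with fewer counts appear to have been left out before deposit. It has no row that names no gene, and the fixed list of mitochondrially encoded genes has 0 members in it. Groups and replicate numbers were taken from the sample titles, and the WT columns of the table were matched to samples through the source names. The columns and source names number the WT libraries differently from the titles. Same-number pairs and the replicate block thus follow the titles alone. The labels do not say that a replicate number marks a shared animal, litter or day. In the data, same-number libraries of the WT and Gα13-deficient groups deviated from their group means together: 3 of 3 pairs correlated above 0.1 (0.111 to 0.179, against -0.12 to -0.021 for other numbers), 6 of 6 libraries correlated best with their own number, and replicate 2 had the female sex pattern in both. For CD97-deficient and WT 0 of 3 pairs did (-0.301 to 0.059; 0 of 6 libraries), and for the knockouts 0 of 3 (-0.073 to 0.011; 1 of 6). The labels give the genotype of the Gα13-deficient libraries as a text that also names Adgre5 deficiency, so both targeted genes are reported in every library first. Nothing in the labels says that the 3 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be partly technical. How the cells were sorted is not given in the sources used here.

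Total counts ran from 5679946 to 13904646 per library, and 3 counts in one library correspond to 0.216 to 0.528 CPM. Symbols were matched to GENCODE mouse release 21 (mm10), 12797 directly and 1211 through a synonym, with 201 unmatched. Genes that overlap on opposite strands cannot be told apart in counts made without strand. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-tests, TMM factors, estimateDisp and glmQLFit with robust estimation) after the default expression filter, which left 12043 genes and removed 2166. All 9 libraries entered 1 fit with the genotype as the factor. The common biological coefficient of variation was 0.15. Adjusted p is by the Benjamini-Hochberg method with a threshold of 0.05 and no fold threshold, and standard errors were computed from the F statistic. CPM values given with a standard deviation are on the TMM scale, n = 3 per group. Fixed gene lists, 32 in all, including markers of other splenic cell types and sex-linked genes, were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and 31 had at least 5 tested genes.

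The list test was tried on a separate draw of counts, and the gene test on simulated counts with 200 changed genes in Adgre5_KO against WT. In that simulation, with 11817 genes in the fit, 19 of 60 genes changed 1.5-fold, 51 of 71 changed 2-fold and 59 of 65 changed 4-fold were recovered, and 9 unchanged genes were called. A list moved 1.5-fold in a simulated Gna13_cKO against WT had an adjusted p of 1.25e-44 with 0 of the other lists past the threshold, among 12043 genes. In the simulated unchanged Adgre5_KO against WT, 1 list passed. Genes were drawn independently, so the list test was not tried on correlated genes. In the real data the estimated correlation was 0.605 for cell cycle genes, CD97-deficient against WT. The covariate fits and the splits of libraries were not simulated. The rule for named genes was fixed before the data were examined, as were the lists, the tests and most alternatives. It takes Adgre5 and Gna13, and for each comparison with WT the 10 largest fold changes per direction among genes with adjusted p under 0.05, a mean log2 CPM of at least 2 and no overlap between the 2 groups. It takes 5 per direction for the direct comparison, 8 per direction for genes called in both comparisons (by the larger of the 2 p-values) and up to 4 members per list discussed. Where fewer than 5 genes met it in a direction, the 5 with the smallest p were taken. For the direct comparison, that fallback was read into the rule after the values had been seen. Symbols of the Gm or Rik type, pseudogenes and ribosomal protein genes were counted and not named by it.

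The alternatives were RLE size factors, library totals alone, no filter, a filter of CPM of at least 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood method, a replicate block, omission of other-cell and sex-linked genes, only the groups compared, an absolute log2 fold change of at least 1, and omission of each library in turn. For lists they also included an estimated correlation and fry. Chosen after seeing the data were the sex pattern of each library (Xist against Y-linked genes) as a covariate, the level of the red pulp macrophage list in each library as a covariate, female-pattern or male-pattern libraries alone, a replicate block with only WT and Gα13-deficient libraries, a correction for GC content and transcript length, and omission of Rn45s, Malat1 and Xist. Figures were drawn with matplotlib.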

Results

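Gene expression was measured by RNA sequencing in splenic cDC2s, the dendritic cell subset that presents antigen mainly to CD4 T cells, from WT, CD97-deficient and Gα13-deficient mice, with 3 libraries per genotype. CD97 is an adhesion G protein-coupled receptor and Gα13 is a G protein subunit that activates RhoA. The 3 WT libraries held 9581458, 7506704 and 5875891 counts, the CD97-deficient ones 8397851, 6805519 and 8689839 and the Gα13-deficient ones 8844470, 5679946 and 13904646. The comparisons ask which genes differ from WT in each knockout, which are shared and which separate the knockouts.

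The targeted genes were read first. Cd97 (chromosome 8, 83723251 to 83741326, mm10) had 1441, 882 and 1302 CPM of the library total in WT replicates 1 to 3, 731, 842 and 451 in the CD97-deficient libraries and 1140, 1240 and 1024 in the Gα13-deficient ones. Its log2 fold change in CD97-deficient cells was -0.89 ± 0.28 (SE, edgeR quasi-likelihood adjusted p = 0.103), which did not pass the threshold, and WT replicate 2 lay close to CD97-deficient replicate 2. The count covers the whole gene, and which part was deleted is not given in the sources used here. Gna13 (chromosome 11, 109362831 to 109401369) had 217, 224 and 186 CPM in WT, 229, 217 and 254 in CD97-deficient and 113, 98.1 and 92.4 in Gα13-deficient libraries. It fell by 1.09 ± 0.11 on the log2 scale in the Gα13-deficient group (adjusted p = 0.000101). Cd97 in that group was near the WT level (log2 fold change -0.13, adjusted p = 0.812), although its label text also names Adgre5 deficiency. All 3 of its libraries lay above the CD97-deficient ones. Since Cd97 RNA did not pass in CD97-deficient libraries either, it does not settle whether the label text holds.

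**Figure D1:**
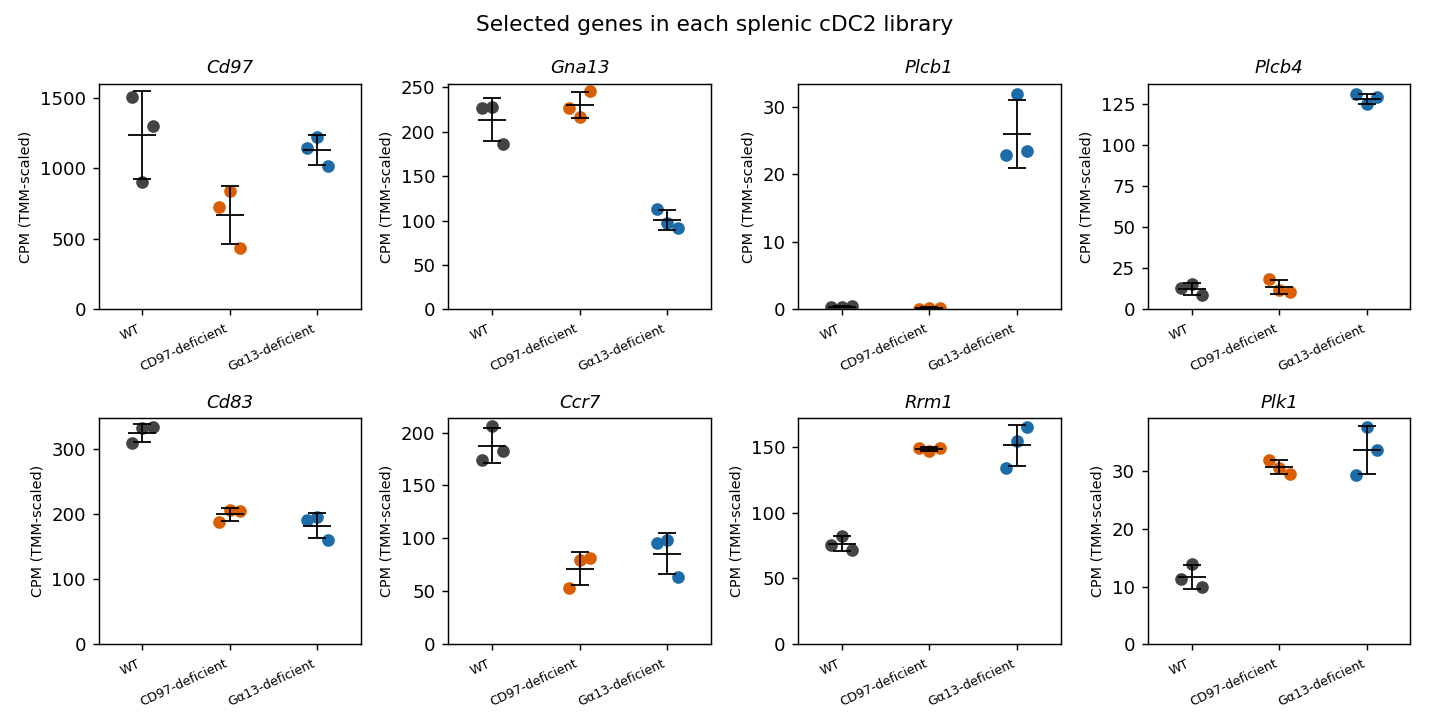
CPM (TMM-scaled, linear axes from 0) of 8 genes in each library, with points for libraries and bars for the mean ± SD of 3. Gna13 averaged 214 in WT and 101 in Gα13-deficient libraries, and Plk1 averaged 11.7, 30.7 and 33.6 in the 3 groups.

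Loss of CD97 came with higher levels of most cell division genes tested and lower levels of part of the dendritic cell maturation genes. Plk1, a mitotic kinase, averaged 11.7 ± 2.03 CPM in WT and 30.7 ± 1.22 in CD97-deficient cells (SD, n = 3 each), a log2 fold change of 1.38 ± 0.16 (SE; adjusted p = 0.000797). Ccr7, the chemokine receptor that guides mature dendritic cells to T cell zones, averaged 187 ± 16.4 against 71.3 ± 15.7 CPM, a log2 fold change of -1.40 ± 0.19 (SE; adjusted p = 0.00269). Cd83, a maturation marker, changed by -0.70 ± 0.09 (SE; adjusted p = 0.000797). In all, 1023 of 12043 genes passed edgeR's quasi-likelihood test, 580 higher and 443 lower. Of these 1014 did not overlap between the groups, nor did 28.2% of all tested genes, against 10% by chance. With library totals in place of TMM factors the split was 766 higher and 341 lower.

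By the rule for named genes, the largest increases after CD97 loss were Serpinb1a (1.82), Dbn1 (1.78), Lgals1 (1.60), Mxd3 (1.59), BC030867 (1.52), Cdc25c (1.46), Dhrs9 (1.41), Stmn1 (1.39), Plk1 (1.38) and Enpp1 (1.38), given as log2 fold changes. Cdc25c, a phosphatase of mitotic entry, and Stmn1, a microtubule regulator, are among genes of dividing cells, and Lgals1 encodes galectin-1. The largest decreases were Ccl4 (-2.66), Lta (-2.00), Abca5 (-1.82), Trim6 (-1.68), Apol7c (-1.63), Insm1 (-1.62), Chic1 (-1.60), Synpo2 (-1.51), Slc27a2 (-1.51) and Bco2 (-1.44). Ccl4 is a chemokine and Lta a cytokine of the TNF family. Of each 10, 6 higher and 6 lower genes passed the threshold in all 9 fits that left out a library, and 5 and 4 passed with the sex pattern of the libraries in the model. Serpinb1a had an adjusted p of 0.04997 and reached 0.209 without WT replicate 1. The highest adjusted p was 0.0884, 0.0915, 0.088 and 0.193 without that library for Lgals1, Dhrs9, Apol7c and Slc27a2, 0.14 without CD97-deficient replicate 1 for Enpp1, and 0.18 and 0.0543 without CD97-deficient replicate 3 for Ccl4 and Abca5. Of the 9 fits, Ccl4 and Slc27a2 were called in 2, Serpinb1a in 3, Dhrs9, Enpp1 and Apol7c in 4, Lgals1 in 6 and Abca5 in 8.

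Of 46 cell cycle genes, 43 rose and none fell (46 rose when adjusted over the list alone), with a median log2 fold change of 0.96. The camera adjusted p was 7.12e-42, and adjusted p = 0.29 with an estimated correlation. The members with the smallest p were Rrm1 (0.96), Plk1 (1.38), Hmgb2 (0.75) and Aurkb (1.09). Of 38 maturation and migration genes, 12 fell and 1 rose (21 and 1 when adjusted over the list alone; camera adjusted p = 6.12e-12; adjusted p = 0.29 with an estimated correlation), led by Cd83 (-0.70), Ccl5 (-1.20), Tmem123 (-0.79) and Ccr7 (-1.40). Cholesterol and lipid genes moved the other way, with 11 of 37 higher and 1 lower (22 and 1 when adjusted over the list alone). The camera adjusted p of that list was 1.54e-10, and adjusted p = 0.29 with an estimated correlation. Its members with the smallest p included Fdft1 (1.08), squalene synthase, and Hmgcs1 (1.23), which makes HMG-CoA, and their calls were lost without CD97-deficient replicate 3 (0.0514 and 0.0542).

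Cytoskeletal targets of MRTF and SRF, transcription factors that respond to actin, had 7 higher and 2 lower genes of 39 after CD97 loss (17 and 2 when adjusted over the list alone). The camera adjusted p was 0.000101, and adjusted p = 0.29 with an estimated correlation. Flna, an actin crosslinker, rose by 0.74 and Myl12a by 0.46, while Tpm1 fell by 0.45. Without CD97-deficient replicate 3 Myl12a (adjusted p 0.0502) and Tpm1 (0.0808) were not called. Of 28 inflammatory and NF-κB genes 6 fell and none rose (11 lower and 1 higher when adjusted over the list alone; camera adjusted p = 1.78e-05; adjusted p = 0.29 with an estimated correlation), among them Traf1 (-0.52), Nfkbiz (-0.76), Il1b (-0.82) and Tnf (-1.09). The interferon list had 7 of 46 lower genes (11 when adjusted over the list alone; camera adjusted p = 3.85e-05; adjusted p = 0.29 with an estimated correlation), and the immediate early list 4 of 28 (4 lower and 1 higher when adjusted over the list alone; camera adjusted p = 1.29e-05; adjusted p = 0.5 with an estimated correlation), the latter led by Nr4a3 (-0.85) and Dusp2 (-0.57). Markers of macrophages, another cell type of the spleen, in a fixed list named for those of the red pulp, had a median log2 fold change of 0.782. In it 1 gene was higher and 2 were lower of 25 (1 and 2 when adjusted over the list alone, camera adjusted p = 0.0349, adjusted p = 0.906 with an estimated correlation). The called members were Cd209b (-2.72), Emr1 (-0.62) and Cd68 (0.32). Nr4a3 was called in 5, Dusp2 in 4 and Cd68 in 6 of the 9 fits that left out a library, and the highest adjusted p was 0.123 and 0.0866 without CD97-deficient replicate 1 for Nr4a3 and Cd68 and 0.141 without CD97-deficient replicate 3 for Dusp2.

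The level of the macrophage list varied between libraries of a group, at -0.55, 0.73 and -1.01 (mean log2 CPM against the mean of all 9 libraries) in WT and 1.02, -0.65 and 0.61 in CD97-deficient replicates 1 to 3. Cell cycle levels were -0.76, -0.38 and -0.87 against 0.32, 0.22 and 0.35 in the same libraries. With the macrophage level in the model 585 genes passed, and the median log2 fold change of cell cycle genes was 0.888 with 42 called, that of maturation genes -0.543 with 12 called. With the replicate block (0.096) and without single libraries the macrophage list lost its call, with adjusted p of 0.155 and 0.359 without WT replicates 1 and 3 and 0.485 and 0.103 without CD97-deficient replicates 1 and 3.

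All 3 CD97-deficient libraries had a female pattern (Xist high, Y-linked genes low) against 1 of 3 WT and 1 of 3 Gα13-deficient libraries, and with that pattern in the model 213 genes passed, the cell cycle list kept a camera adjusted p of 1.52e-45 and the maturation list 3.06e-19, and the macrophage list lost its call (0.762, in the opposite direction, and 0.0838, also in the opposite direction, in female-pattern libraries alone, which hold 1 WT library). Of 85 named genes called after CD97 loss 33 kept their call with the sex pattern, and those that lost it include Fdft1 (0.0927), Hmgcs1 (0.099), Myl12a (0.135), Tpm1 (0.153), Nr4a3 (0.0565), Dusp2 (0.309), Cd209b (0.113), Emr1 (0.0769) and Cd68 (0.161). The count of changed genes was 429 without WT replicate 1, 514 without CD97-deficient replicate 1 and 350 without CD97-deficient replicate 3. It was 1227 without WT replicate 2, the WT library with the female pattern. Sex and loss of CD97 cannot be told apart in that fit.

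The Gα13-deficient group showed a similar set of changes and a small group of very large ones. Whether the other mice carried the Cre transgene is not given in the sources used here. Loss of Gα13 and the transgene thus cannot be separated in this comparison. Plcb4, a phospholipase C, averaged 12.5 ± 3.49 CPM in WT and 128 ± 3.02 in Gα13-deficient cells (SD, n = 3 each), a log2 fold change of 3.34 ± 0.19 (SE; adjusted p = 1.67e-06). Cd83 fell by 0.84 ± 0.09 (adjusted p = 0.000167) and Socs2, a suppressor of cytokine signalling, by 1.47 ± 0.23 (adjusted p = 0.00138). Plk1 changed by 1.51 ± 0.16 (SE; adjusted p = 0.000122). In all 1366 of 12043 genes passed edgeR's quasi-likelihood test, 709 higher and 657 lower, or 868 and 531 with library totals in place of TMM factors. Of the 1366, 1348 did not overlap between the groups, nor did 29.6% of all tested genes, against 10% by chance.

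The largest increases by the rule after Gα13 loss were Plcb4 (3.34), Itgad (2.15), Lgals1 (1.89), Ahnak (1.74), Mxd3 (1.71), Padi2 (1.64), Rbm44 (1.61), Nccrp1 (1.59), Depdc1b (1.56) and Stmn1 (1.55). Plcb1 had a larger change (5.94 ± 0.34, adjusted p = 9.54e-09) at a level under the minimum of the rule. Itgad is an integrin alpha chain of the β2 family and Ahnak a large scaffold protein. The largest decreases were Il1r2 (-2.26), Eps8l1 (-2.18), Apol7c (-2.06), Dnajc22 (-1.84), Nudt17 (-1.76), Trim6 (-1.60), Chic1 (-1.54), Apol10b (-1.53), Mmp12 (-1.51) and Slc12a3 (-1.47). Il1r2 is a decoy receptor for interleukin 1 and Mmp12 macrophage elastase. Of these, 9 of the 10 higher and 8 of the 10 lower genes passed in every fit that left out a library. The exceptions were Ahnak, Il1r2 and Eps8l1, called in 2, 5 and 6 of the 9 fits. Their highest adjusted p was 0.133 without WT replicate 1 for Ahnak, and 0.085 and 0.068 without Gα13-deficient replicate 3 for Il1r2 and Eps8l1. With a replicate block in the 2 groups Ahnak had an adjusted p of 0.0915.

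Of the 46 cell cycle genes, 44 rose and none fell in Gα13-deficient cells (45 when adjusted over the list alone), with a median log2 fold change of 1.02, a camera adjusted p of 5.19e-42, and adjusted p = 0.308 with an estimated correlation. Rrm1, a ribonucleotide reductase subunit, rose by 0.98 and Aurkb, a mitotic kinase, by 1.20. Maturation and migration genes fell in 21 of 38 cases and rose in 1 (29 and 1 when adjusted over the list alone; camera adjusted p = 3.69e-15; adjusted p = 0.308 with an estimated correlation), with Cd83 (-0.84), Tmem123 (-0.95), Nudt17 (-1.76) and Socs2 (-1.47) at the smallest p. MRTF and SRF targets included 10 higher and 2 lower genes of 39 (18 and 2 when adjusted over the list alone; camera adjusted p = 0.000525; adjusted p = 0.385 with an estimated correlation), with Flna (0.74), Vcl (0.48) and Actn4 (0.49) higher and Tpm1 (-0.46) lower. In the MHC class II list 4 of 21 genes fell (4 when adjusted over the list alone; camera adjusted p = 0.0494; adjusted p = 0.772 with an estimated correlation), namely H2-Eb2 (-0.89), H2-Ob (-0.72), Rfx5 (-0.38) and H2-Oa (-0.42); H2-Ob and H2-Oa encode the peptide-loading modulator H2-O. That call was lost without WT replicate 2 (adjusted p 0.058), CD97-deficient replicates 1, 2 and 3 (0.0566, 0.0646 and 0.0613) and Gα13-deficient replicates 2 and 3 (0.0872 and 0.107), with the macrophage level in the model (0.0739) and with a replicate block in the 2 groups (0.0952). Tpm1 was not called without Gα13-deficient replicate 2 (0.0503), and H2-Oa reached 0.0596 without WT replicate 3.

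Markers of plasmacytoid dendritic cells had 3 higher and no lower genes of 19 in Gα13-deficient cells (5 and 0 when adjusted over the list alone; camera adjusted p = 0.00391; adjusted p = 0.82 with an estimated correlation), with Cox6a2 (2.89) and Tcf4 (0.41) at the smallest p. In the female-pattern libraries alone its direction was the opposite (adjusted p 0.774), in a comparison of 1 library with 1, which is too small to show a turned direction. Cox6a2 (chromosome 7, 128205435 to 128206387) lies within the span of Itgad (128154376 to 128223816) on the other strand, so reads of the 2 genes cannot be told apart without strand. The cholesterol list also passed (1 higher and 1 lower of 37; 0 and 1 when adjusted over the list alone; camera adjusted p = 0.00555; adjusted p = 0.82 with an estimated correlation), its called members being Mylip (-0.75), which degrades the LDL receptor, and Cd36 (1.02), a fatty acid transporter. It did not pass without WT replicate 1 (adjusted p 0.213). Tcf4 reached 0.0673 without Gα13-deficient replicate 1. Cd36 was called in 3 of the 9 fits that left out a library (highest 0.144 without Gα13-deficient replicate 1), and not with the sex pattern (0.062) or a replicate block in the 2 groups (0.0783). The count of changed genes was 768 without Gα13-deficient replicate 2. It was 561 in the male-pattern libraries alone (2 against 2) and 156 in the female-pattern ones (1 against 1, with the spread taken from the CD97-deficient libraries), where the log2 fold change of Cd36 was -0.033 and its call was lost.

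**Figure D2:**
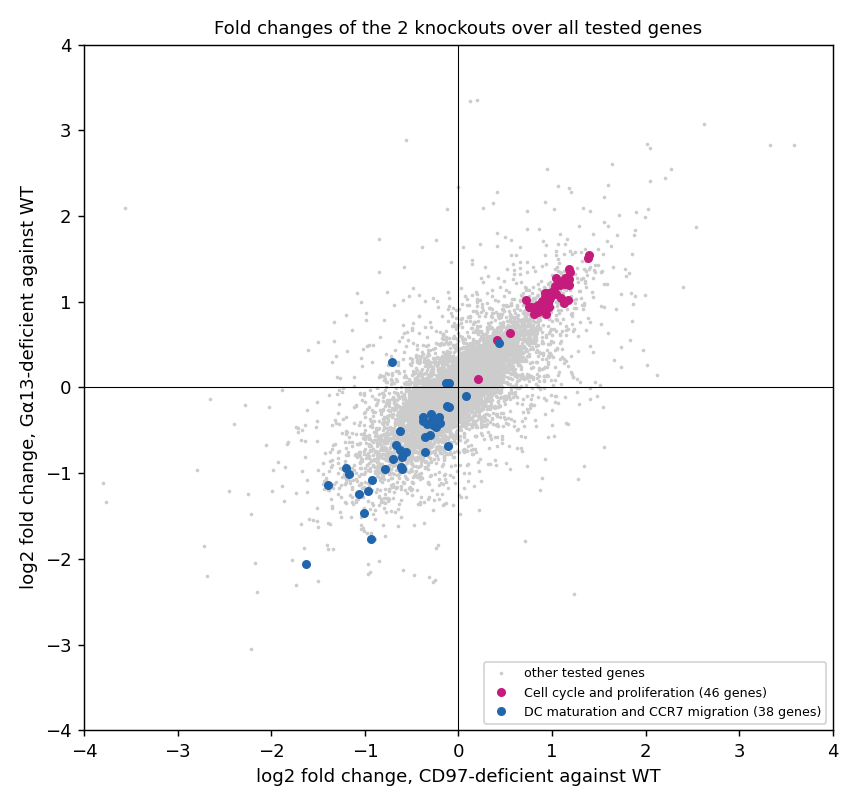
Log2 fold changes of CD97-deficient (horizontal) and Gα13-deficient (vertical) against the same WT libraries over 12043 genes, with the 46 cell cycle and 38 maturation genes coloured and 14 genes outside the axes. The cell cycle genes sit in the upper right and most maturation genes in the lower left, with medians of 0.96 and -0.475 for CD97 loss.

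Of 46 cell cycle genes 43 and 44 rose after loss of CD97 and of Gα13, and of 38 maturation genes 12 and 21 fell and 1 rose in each. For both lists, adjusted p = 0.29 and 0.308 with an estimated correlation, past the threshold in neither comparison. By fry, adjusted p was 0.0125 and 0.00533 for cell cycle genes and 0.0142 and 0.00533 for maturation genes. Fry asks whether a list moves at all and does not compare it with the other genes. In both comparisons 740 genes passed in the same direction, 446 higher and 294 lower, and 0 passed in opposite directions (1 at an unadjusted p under 0.05 in both, and 1 by DESeq2). With independent lists of these sizes 34.1 higher and 24.2 lower would be shared. By the rule, the higher ones were Rrm1, Cdca3, Plk1, Flna, Vim, Foxm1, Anln and Hmgb2. Their log2 fold changes were between 0.74 (Flna) and 1.51 (Plk1) in the 2 comparisons. The lower ones were Gbp8, Zfc3h1, Cd83, Tnfrsf11a, Malat1, Tmem123, Birc2 and Traf1, with Malat1, a nuclear long noncoding RNA, at 38376 ± 3894 CPM in WT, 22276 ± 1419 in CD97-deficient and 25589 ± 1015 in Gα13-deficient libraries (SD, n = 3 each). Birc2 and Traf1 act in TNF receptor signalling. All 16 passed in each of the 9 fits that left out a library and with the sex pattern in the model, for both comparisons.

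Because both comparisons share 3 WT libraries that cannot be divided into parts of 2 libraries each, part of the excess may come from them. If the Gα13-deficient libraries also lacked Adgre5, as their label text reads, they would share changes of CD97 loss for that reason. The Cd97 counts do not settle this. In 20 simulations of unchanged groups against the same controls, 0 genes were called in both in every one. With no gene changed hardly any can be called in either comparison, so this 0 does not measure the part from the controls. Genes were drawn independently of each other, with no sex or replicate effect. The correlation of log2 fold changes across genes was 0.681, against a mean of 0.504 in those simulations, and the covariance 0.152 against 0.041, a difference of 0.111. The simulations gave all groups the same spread per gene. In the data, chi-square per degree of freedom between 2 libraries was 12.72 to 21.04 in WT. It was 6.4 to 6.62 in CD97-deficient and 10.37 to 15.23 in Gα13-deficient libraries. The simulated values may thus be too low and the difference too high. The mean of both knockouts against WT gave 1797 genes, 906 higher and 891 lower (1133 and 692 with library totals), and 1143 genes differed among the 3 genotypes. Without WT replicate 1 these counts were 959 and 626, and the latter 752 without Gα13-deficient replicate 2. The overlap was 201 genes with the sex pattern in the model, 480 with the macrophage level, 363 without WT replicate 1, and 410, 322 and 487 without CD97-deficient replicates 1 and 3 and Gα13-deficient replicate 2.

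Between the knockouts themselves few genes separated in the fit of all 9 libraries, where the spread is estimated with the WT libraries included. With only the 2 groups compared 49 genes passed, so the small number depends on the fit. Higher in Gα13-deficient cells were Plcb1 (log2 fold change ± SE 7.15 ± 0.39, adjusted p = 3.34e-09), Plcb4 (3.22 ± 0.19, adjusted p = 2.05e-06), Cox6a2 (3.46 ± 0.37, adjusted p = 0.000666) and Xdh (1.22 ± 0.19, adjusted p = 0.0393), and Gna13 was lower (-1.19 ± 0.11; adjusted p = 7.13e-05). Plcb1 and Plcb4 are phospholipase C genes next to each other on chromosome 2 (134786067 to 135475258 and 135659011 to 136014593), and Plcb1 had 9 counts in the 3 WT libraries, 4 in the CD97-deficient and 712 in the Gα13-deficient ones. Xdh, xanthine dehydrogenase, averaged 16.9 ± 2.81, 8.89 ± 1.44 and 20.7 ± 3.48 CPM in the 3 groups. Next by p were Egr2 (2.05 ± 0.30, adjusted p = 0.0718), and, lower, Lphn3, Slc7a11, Rasgrp3 and Fn1, with adjusted p of 0.0585, 0.0918, 0.101 and 0.101, none past the threshold.

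Immediate early genes were the list that separated the knockouts at the smallest p: 0 of 28 passed over all genes by edgeR's quasi-likelihood test, 17 had an unadjusted p under 0.05, DESeq2 called 6, and 13 passed when adjusted over the list alone, all higher in Gα13-deficient cells, with a median log2 difference of 0.62 (camera adjusted p = 1.27e-20; adjusted p = 0.35 with an estimated correlation). Egr2 and Klf4 (0.59; adjusted p = 0.0823), both transcription factors, had the smallest p in it. Heat shock genes, a sign of stress during dissociation, had a median of 0.432 with 0 of 19 called by edgeR, 2 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 5.60e-06; adjusted p = 0.465 with an estimated correlation), and the list did not pass with the sex pattern in the model (0.161). Cholesterol genes had a median of -0.367 with 0 called of 37 by edgeR, 13 lower at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 5.20e-11; adjusted p = 0.35 with an estimated correlation). The plasmacytoid list had 1 higher gene of 19, Cox6a2, and 2 when adjusted over the list alone (camera adjusted p = 4.17e-07; adjusted p = 0.35 with an estimated correlation). The cell cycle list had a median of 0.1 with 0 of 46 called by edgeR, 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone (camera adjusted p = 0.00718; adjusted p = 0.653 with an estimated correlation), and did not pass without CD97-deficient replicate 2 (0.147) or without Gα13-deficient replicate 3 (0.955, in the opposite direction).

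None of the list results in any of the 3 comparisons passed camera with an estimated correlation. In total 5 genes passed edgeR's quasi-likelihood test between the knockouts and 766 had an unadjusted p under 0.05, while DESeq2 called 57. None of the 5 overlapped between the groups, nor did 13.1% of all tested genes, against 10% by chance. The count was 15, 27 and 12 without WT replicates 1, 2 and 3 and 16 without Gα13-deficient replicate 3. Xdh was called in 4 of the 9 fits that left out a library and not without any one of CD97-deficient replicates 1, 2 and 3 and Gα13-deficient replicates 1 and 3 (highest adjusted p 0.294), and with the sex pattern in the model Xdh (adjusted p 0.539) and Cox6a2 were not called. With that pattern the median size of the log2 fold changes of the 5 genes went from 3.218 to 3.288. Their median standard error rose from 0.193 to 0.255.

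**Figure D3:**
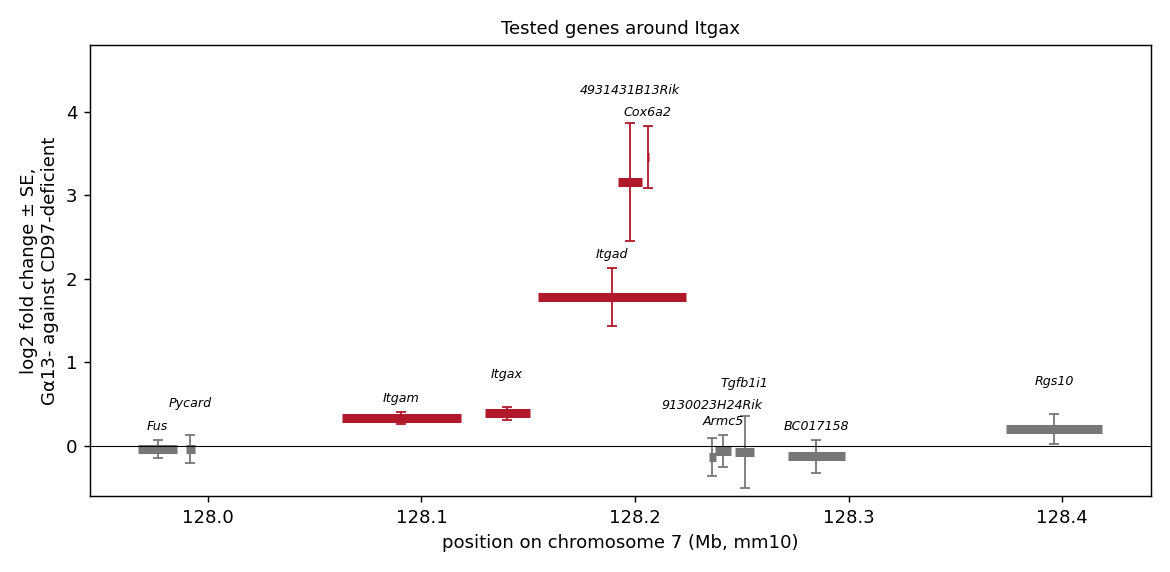
Log2 fold change ± SE of Gα13- against CD97-deficient libraries (3 each) for tested genes around Itgax on chromosome 7 (mm10), drawn at their annotated extent. Genes from Itgam to Cox6a2 (red) lie between 0.34 and 3.46, and the 7 outside genes (grey) between -0.13 and 0.20.

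**Figure D4:**
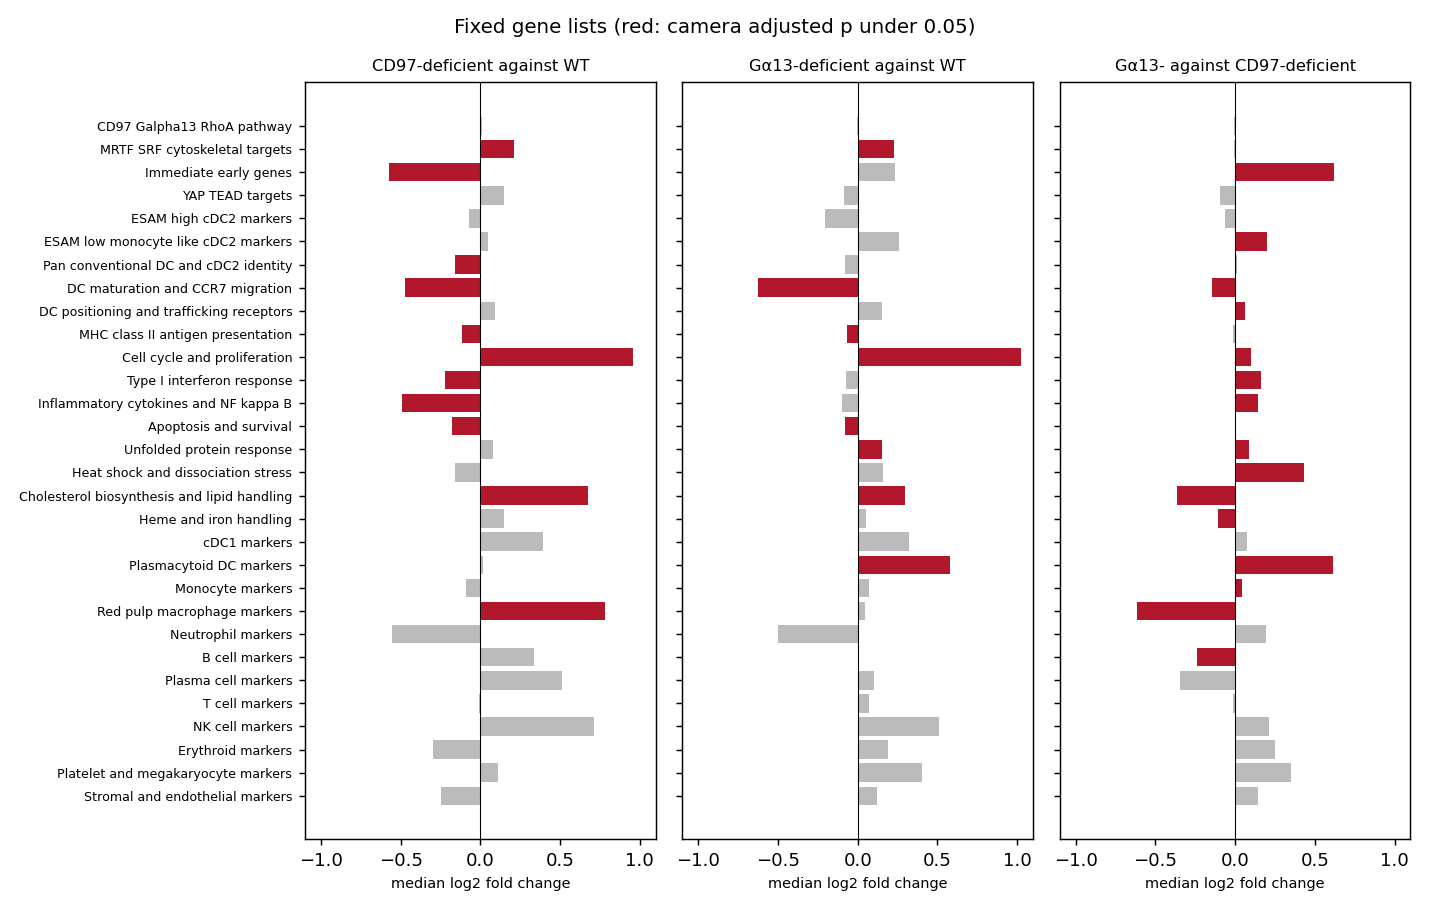
Median log2 fold change of each of 30 fixed lists in the 3 comparisons, with red bars for a camera adjusted p under 0.05 at the preset correlation. No list passed with an estimated correlation. The cell cycle bars reach 0.96 and 1.02 against WT and 0.1 between the knockouts.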

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

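Tests of the segment and stretch on chromosome 7, of the chromosome 2 segment, of macrophages and other cell types, handling, single libraries and sex were chosen after the results they bear on had been seen. Those of exchanged labels and of other splits of the libraries were chosen before.

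The 5 genes whose direct test separated the knockouts are Plcb1 (log2 fold change 7.15), Cox6a2 (3.46), Plcb4 (3.22), Xdh (1.22) and Gna13 (-1.19), in Gα13-deficient against CD97-deficient libraries. Other splits of the 6 libraries gave up to 31 genes (CD97-deficient replicates 1 and 2 with Gα13-deficient replicate 3), so 2 of the 10 splits gave as many as the 5 genes of the labelled one. That split called several times as many, which points to a structure among these libraries, and 10 splits are too few for a share under 0.05. For CD97-deficient against WT, 1 of 10 splits (the labelled one, 1023 genes) reached the count, with 93 as the highest other. For Gα13-deficient against WT, 1 of 10 did (1366 genes), with 1 as the highest other, and those 10 splits too cannot give a share under 0.05. Of those 10, 4 part all 3 same-number pairs, the labelled one and 3 that gave 0 genes each, and the other 6 part 1 pair. For the mean of both knockouts against WT, in a fit with 2 groups (1761 genes as labelled), 1 of 84 splits reached that count. The highest other gave 54, so a random regrouping of the libraries is argued against as the source, as far as the libraries are independent. These splits take the libraries as independent, which the labels do not state. They also ignore that same-number WT and Gα13-deficient libraries went together. For the 3 genotypes, 2 of 100 splits reached 1143 genes, the labelled one included. That share is under 0.05 if the libraries are independent, but a regrouping did reach the count. The other one, with 1260 genes, kept the WT libraries together and mixed the knockouts. Further drawn splits that did so gave 782 and 783 genes. The count thus reflects WT against the rest, and it does not show that the 2 knockouts differ from each other.

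The first pattern is the higher level of Plcb1, Plcb4, Cox6a2 and Itgad in Gα13-deficient libraries. Itgad passed against WT but not against CD97-deficient libraries (log2 fold change 1.78, unadjusted p = 0.00139 by edgeR's quasi-likelihood test). A single odd library is argued against, since at least 95.3% of the log2 fold change of each of the 4 genes against CD97-deficient libraries was left without any one Gα13-deficient library. A raised block of 200 kb on each side of Cox6a2 and Itgad is argued against (median of 10 neighbours at percentile 31.8 of runs of neighbouring genes), while a block over the narrower stretch from Itgam to Cox6a2 stays open, since 5 of its 5 genes were higher at an unadjusted p under 0.05, but Cox6a2 and 4931431B13Rik lie within Itgad and may share its reads, and with overlapping genes counted once the stretch holds 3 genes and 3 other runs hold as many. A raised block on chromosome 2 stays open too, since no more than 3 other tested genes lie within 1000 kb of Plcb1 and Plcb4 and none between them (percentile 65.9). A candidate explanation for the stretch, not tested, is extra copies of the Itgax region carried by the CD11c-Cre transgene. Against CD97-deficient libraries Itgax itself was higher by 0.39 on the log2 scale, while Itgad was by 1.78 and Cox6a2 by 3.46. Whether the WT and CD97-deficient mice carried Cre is not given in the sources used here. The transgene and loss of Gα13 itself, an untested biological explanation, thus cannot be separated.

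The second pattern is the rise of most cell cycle genes (43 and 44 of 46) and the fall of part of the maturation genes (12 and 21 of 38, with 1 higher in each) in CD97-deficient and Gα13-deficient cells. Exchanged labels of WT replicate 2 and CD97-deficient replicate 2, whose Cd97 counts were close, are argued against, since exchanging them gave 93 genes in place of 1023. Handling that lowers immediate early genes is argued against as the shared cause. Their median log2 fold change was -0.571 ± 0.094 (SE) in CD97-deficient but 0.234 ± 0.146 in Gα13-deficient cells. Of the called genes of that list, Nr4a3 and Gadd45b fell in both, while Klf4 and Klf2 rose in Gα13-deficient cells. Handling that does not lower this list was not tested. Red pulp macrophages carried into the knockout libraries, read by their list, are argued against for CD97-deficient cells. With the list's level in the model at least 92.6% of the median log2 fold changes of both lists was left in both comparisons. The macrophage list's own median fell from 0.782 to 0.144 in CD97-deficient cells. In Gα13-deficient cells that median was 0.043 before the covariate, so macrophage markers were hardly raised and the covariate had little to remove. Cycling cells of some other type stay open, since the highest median among the lists of other cell types apart from macrophages (0.713 ± 0.341 SE, 8 NK cell genes, CD97-deficient against WT) lay within its SE of that of cell cycle genes (0.96), although in Gα13-deficient cells the highest (0.58 ± 0.299, plasmacytoid cells) did not reach 1.02, and cells without a list were not tested, and so do the genotypes themselves, the biological explanation that the design names.

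The third pattern is the drop from 1023 to 213 genes in CD97-deficient against WT with the sex pattern in the model. With the covariate 89.7% of the median log2 fold change of the called genes was left, which does not settle whether sex is the cause. The effect of the covariate was read from WT and Gα13-deficient libraries alone, since all 3 CD97-deficient ones had the female pattern. In those 2 groups the female pattern was that of replicate 2, and same-number libraries went together. Sex and a replicate effect thus cannot be told apart. The 82.3% left in the female-pattern libraries alone, with 1 WT library, decides nothing either. The median size went from 0.615 to 0.552 while the median standard error rose from 0.133 to 0.158, and 1023 of 1023 genes kept their sign. With the smaller fold changes and the earlier standard errors 784 genes would pass, and with the earlier fold changes and the larger standard errors 354, so each of the 2 ends calls and the standard errors end more. How much of the fold changes comes from sex stays open, since all 3 CD97-deficient libraries and no more than 1 WT library had the female pattern.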

How the results depend on the processing

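The sex-pattern, macrophage-level, female-pattern, male-pattern, GC and abundant-gene alternatives and the block in 2 groups were chosen after seeing the data. Among fits that left out a library, the one without WT replicate 2 gave the highest gene counts. There the WT libraries had the male pattern and the CD97-deficient ones the female pattern. For CD97-deficient against WT, 1023 genes became 213 with the sex pattern, 585 with the macrophage level, 192 in female-pattern libraries and 177 at an absolute log2 fold change of at least 1, and 350 to 1227 over the fits that left out a library. For Gα13-deficient against WT, 1366 became 156 in female-pattern and 561 in male-pattern libraries and 307 with the fold threshold, and 768 to 1468 over the left-out libraries. Between the knockouts, 5 became 57 with DESeq2, 15 with the replicate block, 15 with the macrophage level, 3 with the sex pattern, 17 in female-pattern libraries and 49 with only the 2 groups compared, and 4 to 27 over the left-out libraries. For the mean of both knockouts, 1797 became 1093 with the sex pattern, 245 in female-pattern libraries and 281 with the fold threshold, and 959 to 1730 over the left-out libraries. For the 3 genotypes the range was 626 to 1196. The overlap of 740 became 201, 480, 105 and 112 under the sex pattern, macrophage level, female-pattern libraries and the fold threshold, and 322 to 899 over the left-out libraries. The stricter threshold accounts by construction for the fold results, the female-pattern libraries compare 1 Gα13-deficient with 1 WT library (each assumed to vary like the CD97-deficient ones) and the male-pattern libraries 2 with 2, too few to show a dependence on sex, values on the sex pattern in CD97-deficient against WT are given with the third pattern, and for the rest the cause was not tested. Lists past the threshold were 11, 8 and 15 in the 3 comparisons and 0, 0 and 0 with an estimated correlation; fry gave 3 for Gα13-deficient against WT and 0 between the knockouts, male-pattern libraries 15 for the former and female-pattern libraries 7 for the latter. For CD97-deficient against WT fry gave 8 lists. Over the left-out libraries the lists past the threshold by camera were 8 to 12, 5 to 11 and 11 to 16. Directions turned for red pulp macrophage markers with the sex pattern (adjusted p 0.762 for CD97-deficient against WT and 0.325 between the knockouts) and, for the former, in female-pattern libraries (0.0838), for the latter with the macrophage level (0.561), plasmacytoid markers for Gα13-deficient against WT in female-pattern libraries (0.774), cell cycle genes between the knockouts without Gα13-deficient replicate 3 (0.955, range 1.3e-08 to 0.955 over the left-out libraries), and Cd36 (-0.033) and Ly6c2 (-0.223) for Gα13-deficient against WT in female-pattern libraries; the cause was not tested. With the replicate number as a block and only Gα13-deficient and WT libraries, where the numbers go together, 1165 genes and 10 lists passed. The MHC class II list (0.0952) and 8 of 100 named genes, among them Ahnak, Cd36 and Msn (0.0915, 0.0783 and 0.0675), lost their calls there, the immediate early, ESAM-high and heat shock lists (0.0317, 0.0392 and 0.0482) passed, and no other list changed its call. In the other 2 comparisons the libraries share a number only. With the block in all 9 libraries the counts were 1051, 1354, 1774 and 1184 against WT, for the mean and for the 3 genotypes. Of the named genes called, 44 of 85, 72 of 100 and 4 of 5 passed in all fits that left out a library, and 33 of 85, 96 of 100 and 3 of 5 with the sex pattern. At the depths of these libraries simulated 1.5-fold changes were recovered for 31.7% of genes.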

Other observations

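Some genes in the lists of cDC2 subset markers changed, and none of these lists passed as a whole against WT. In the list of markers of ESAM-high cDC2s 5 of 23 genes fell and 1 rose in Gα13-deficient cells (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0588, but 0.0478 with the replicate block, 0.0392 with it in the 2 groups alone, 0.0286 without WT replicate 2 and 0.0285 and 0.0408 without Gα13-deficient replicates 1 and 2), among them Adam23 (-0.76), Lrrk1 (-0.50) and Gpr4 (-0.67) lower and Tbx21 (0.61), the transcription factor T-bet, higher. In CD97-deficient cells 4 of 23 fell and none rose (5 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.179), including Adam23 (-0.50) and Bcl6 (-0.31). Of 34 markers of monocyte-like ESAM-low cDC2s, 4 rose and 2 fell in Gα13-deficient cells (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0734, but 0.0286 without WT replicate 2 and 0.027 and 0.0373 without Gα13-deficient replicates 2 and 3), with Klf4 (0.92) and the chemokine receptor Cx3cr1 (1.54) higher and Il18rap (-1.45) and Tlr7 (-0.61) lower. In CD97-deficient cells 1 rose and 5 fell (4 and 5 when adjusted over the list alone; camera adjusted p = 0.713), with Tlr7 (-0.58) and Il18rap (-1.26) among the lower ones. Among identity genes, Cd24a rose in both knockouts (1.13 and 1.36) and Dpp4 (-0.39 and -0.49) and Csf2rb (-0.51 and -0.60) fell in both. With the sex pattern in the model no gene named here was called after CD97 loss, with adjusted p of 0.0555 for Adam23, 0.302 for Bcl6, 0.17 for Tlr7, 0.0673 for Il18rap, 0.0646 for Cd24a, 0.078 for Dpp4 and 0.0783 for Csf2rb. Bcl6 was called in 2 of the 9 fits that left out a library and Tlr7 and Il18rap in 7, with the highest adjusted p (0.187, 0.0796 and 0.0637) without CD97-deficient replicate 3. After Gα13 loss Gpr4 reached 0.0525 without WT replicate 1 and Tbx21 0.0613 without Gα13-deficient replicate 2.

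Among trafficking receptors, the integrin chain Itgb7 rose by 0.45 in CD97-deficient and 0.51 in Gα13-deficient cells, and Gpr132 (-0.53 and -0.70), Emr1 (-0.62 and -0.73) and Ccr7 (-1.40 and -1.14) fell in both, by edgeR's quasi-likelihood test. After CD97 loss Gpr132 was called in 5 of the 9 fits that left out a library (highest adjusted p 0.0861 without CD97-deficient replicate 1), and with the sex pattern in the model Itgb7 (0.056), Gpr132 (0.217) and Emr1 (0.0769) were not called while Ccr7 was (0.0104). The list of 41 as a whole did not pass in either comparison with WT (camera adjusted p = 0.9 and 0.174). The list of the CD97, Gα13 and RhoA pathway did not pass in either comparison with WT. It had 3 higher and 2 lower of 26 genes in Gα13-deficient cells (3 and 2 when adjusted over the list alone; camera adjusted p = 0.941) and 2 higher and 0 lower in CD97-deficient cells (3 and 0 when adjusted over the list alone; camera adjusted p = 0.733). Cfl1 (0.51 and 0.44) and Msn (0.32 and 0.25), which encode cofilin and moesin, rose after loss of CD97 and of Gα13. After CD97 loss the call for Msn was lost without CD97-deficient replicate 3 (log2 fold change 0.277). After Gα13 loss it was lost without WT replicate 3 (0.233), CD97-deficient replicate 1 (0.255) and Gα13-deficient replicates 1 and 2 (0.233 and 0.229), and that for Cfl1 without Gα13-deficient replicate 2 (0.394). With the sex pattern in the model neither Msn (adjusted p 0.16) nor Cfl1 (0.104) was called after CD97 loss, and Msn was not called after Gα13 loss with a replicate block in the 2 groups (0.0675). Besides Gna13, Arhgef12, a RhoA exchange factor downstream of Gα13, fell by 0.98 in Gα13-deficient cells (adjusted p = 0.00361), and its value in CD97-deficient cells was -0.50 (adjusted p = 0.0957). The direct test of the difference in Arhgef12 (-0.48; adjusted p = 0.688) did not pass, which does not show that the 2 effects were equal.

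Of the other fixed lists, apoptosis and survival genes had 6 lower and 2 higher of 34 after CD97 loss (7 and 2 when adjusted over the list alone; camera adjusted p = 0.00626; adjusted p = 0.29 with an estimated correlation; 0.0588 without WT replicate 2) and 7 lower and 2 higher after Gα13 loss (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0428; adjusted p = 0.692 with an estimated correlation; 0.177 without WT replicate 2, 0.0584 and 0.0613 without CD97-deficient replicates 2 and 3, 0.0516 without Gα13-deficient replicate 1 and 0.0524 with the sex pattern in the model). Identity genes of conventional dendritic cells passed as lower after CD97 loss, with 3 higher and 6 lower of 25 (3 and 10 when adjusted over the list alone; camera adjusted p = 0.0459; adjusted p = 0.5 with an estimated correlation). That call was lost without WT replicates 2 and 3 (0.0567 and 0.078) and CD97-deficient replicates 1 and 3 (0.108 and 0.145). MHC class II genes also passed as lower, with 1 of 21 called (1 when adjusted over the list alone; camera adjusted p = 0.0459; adjusted p = 0.466 with an estimated correlation). That call was lost without WT replicates 2 and 3 (0.0567 and 0.0985), CD97-deficient replicates 1 and 2 (0.0765 and 0.0843) and Gα13-deficient replicates 2 and 3 (0.0503 and 0.0533). Neither list passed with the sex pattern in the model (0.0663 and 0.191) or with the macrophage level (0.0927 and 0.0885). Unfolded protein response genes had 4 higher and 2 lower of 26 after Gα13 loss (9 and 2 when adjusted over the list alone; camera adjusted p = 0.0424; adjusted p = 0.82 with an estimated correlation) and did not pass without WT replicate 3 (0.109), CD97-deficient replicate 2 (0.0503) or Gα13-deficient replicate 1 (0.103).

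Between the knockouts the ESAM-low list (3.60e-07), the interferon list (2.03e-05) and the inflammatory list (0.000298) were higher in Gα13-deficient cells by camera, with 0 called genes each by edgeR (6, 9 and 7 higher at an unadjusted p under 0.05) and 4 when adjusted over each list alone, and adjusted p = 0.35 with an estimated correlation for each. Macrophage markers were lower there (median -0.614; 0 of 25 called and 0 when adjusted over the list alone; camera adjusted p = 0.000658; adjusted p = 0.549 with an estimated correlation), and did not pass without CD97-deficient replicate 1 (0.51) or Gα13-deficient replicate 3 (0.176), and turned to the opposite direction with the sex pattern (0.325) or the macrophage level (0.561) in the model. Another 6 lists passed camera with 0 called genes each. Higher were unfolded protein response genes (1 higher of 26 when adjusted over the list alone; camera adjusted p = 0.00525), trafficking receptors (2 higher of 41; 0.0108) and monocyte markers (2 higher and 1 lower of 22; 0.0125). Lower were maturation genes (0 of 38; 0.00313), B cell markers (1 lower of 19; 0.0145) and heme and iron genes (1 lower of 24; 0.0469). For these 6, adjusted p = 0.465 with an estimated correlation, except 0.522 for heme and iron genes. The call for trafficking receptors was lost without CD97-deficient replicate 2 (0.0506) or Gα13-deficient replicate 1 (0.193), and that for monocyte markers without CD97-deficient replicate 2 (0.367). The maturation call was lost without CD97-deficient replicate 3 (0.0665) or Gα13-deficient replicate 3 (0.444), and the B cell call without the same libraries (0.418 and 0.424). The heme and iron call was lost without CD97-deficient replicates 1 and 3 (0.432 and 0.361) and Gα13-deficient replicate 3 (0.32). With the sex pattern in the model the maturation, B cell and heme and iron calls ended (0.795, 0.202 and 0.795), as they did with the macrophage level (0.0508, 0.0529 and 0.533), and the heme and iron call also ended with the replicate block (0.0817).

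Of the lists of other cell types, those of monocytes, cDC1s, neutrophils, B cells, plasma cells, T cells, NK cells, erythroid cells, platelets and stroma passed in neither comparison with WT (neutrophils did with the replicate block after CD97 loss, 0.0318), nor did YAP and TEAD targets or heme and iron genes.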
